A study of Mus musculus and Adeno-associated virus 9 with 25 samples.

How the data were processed

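The samples came from a massively parallel reporter assay (MPRA), in which each tested sequence is placed upstream of a minimal promoter and a reporter that carries a short barcode, and the barcodes are counted in RNA and in DNA. The reporters were packed in AAV9, an adeno-associated virus that transduces neurons and other brain cells. Per the labels, the virus was injected into the hippocampus of adult mice, 2 µL at each of 4 sites, and tissue was taken 28 days later. RNA was made from total hippocampus and from a Vglut1 fraction by translating ribosome affinity purification (TRAP), which pulls down GFP-tagged ribosomes of 1 cell class, here cells that express Vglut1, the vesicular glutamate transporter of excitatory neurons. Per the labels, the supernatant was split between the total RNA and the pull-down. DNA came from the virus lysate, measured in 4 technical repeats of 1 lysate.

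The processed data held 1 raw read count per barcode and library, as deposited by the authors, with no normalization and with empty cells where no read was counted. These empty cells were read as 0. Whether the values were raw counts was checked on the values, which are whole numbers with different library totals. The tool that counted the barcodes is not given in the sources used here. The build hg19 is named per the submitters' processing notes, with no role stated. A second table, as deposited, gave the sequence and the identifier of each of the 29280 designed barcodes, and all 29280 matched a barcode of the count table when read as the reverse complement. Identifiers name the source study, the locus, the variant and the allele. No chromosome positions were used here, and which allele is the reference was not known, so allele effects are allele 2 minus allele 1 in alphabetical order, with a deletion, written as a dash, first.

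The design held 1454 variants from 41 loci, with 10 barcodes of 10 bases for each of 2908 alleles, 110 barcodes named Basal, read here as the minimal promoter with no insert because no insert sequence is listed for them, and 9 other control sequences. The cloned sequence was 126 bases long in 96.5% of elements. Groups were taken from the labels: female and male total hippocampus and female and male Vglut1, 5 libraries each. Male total replicate 3 was sequenced in 2 runs, which were summed, since their departures from the other male total libraries correlated at r = 0.923 across barcodes. Every per-sample column was used (0 left out). In 3 Vglut1 libraries the label starts with MAX, whose meaning is not stated (female replicate 4, male replicates 4 and 6). Of the barcodes with at least 100 DNA counts, 143 had no count in male Vglut1 6 and 39 in male Vglut1 4. Female Vglut1 4 had 12 such barcodes, and the other RNA columns at most 34 (female total 2).

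Barcodes with at least 100 counts over the 4 DNA libraries were kept, and alleles with at least 5 such barcodes. This kept 24721 barcodes (84.4%, with 99.6% of DNA counts), 2724 alleles and controls, and 1286 variants with both alleles. The other 4559 barcodes were below that minimum or belonged to alleles with too few such barcodes, and were left out because ratios from few DNA counts or few barcodes are imprecise. Counts were summed per allele and library. The RNA share was divided by the share in the summed DNA, which entered as a fixed offset and not as replicates.

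Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and the plots used Python 3.11.15 with matplotlib 3.10.9. Activity, sex, fraction and sex by fraction were tested with edgeR quasi-likelihood F-tests on allele sums, with TMM factors and 1 coefficient per group, so that all 20 RNA libraries enter the spread of each allele. Activity is the mean over the 4 groups against Basal. Fraction is Vglut1 minus total as a mean of both sexes. Allele effects used 1 line per variant with both alleles of each library, a library term and an allele coefficient per group, again in edgeR. They were also tested across barcodes: each barcode's mean over the 10 libraries of a fraction of log2((RNA CPM + 1)/(DNA CPM + 1)), where CPM is counts per M, was compared between the alleles with limma's moderated variance. All p-values are two-sided, and adjusted p-values are Benjamini-Hochberg values over all alleles or variants tested, with a threshold of 0.05. In the tests across animals the p-values measure the spread between samples, which does not hold the effect a barcode has in every animal. In the tests across barcodes they measure the spread between barcodes.

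Sequence groups were 36 lists fixed beforehand: 33 consensus motifs of transcription factors and core promoter boxes, matched on either strand of either allele, and 3 lists by GC or CpG content. Lists with at least 10 variants were tested with camera (preset correlation 0.01, and again with an estimated correlation) on the mean of both alleles per variant, with activity taken relative to the median variant. For motifs that only 1 allele of a variant carries, the mean effect (motif-bearing minus other allele) was tested with a sign-flip permutation test with 100000 resamples, or an exact one with under 10 variants, where at least 6 variants could be used.

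The alleles and variants named were set by rule: for activity the 10 highest and 5 lowest past the threshold, for allele effects up to 10 past the threshold both across animals and across barcodes, and for the other comparisons the 5 largest in each direction, or the 3 with the smallest p where none passed. Where none passed across barcodes, the 3 with the smallest p are given. The groups, comparisons, filters, lists, the naming rule and most alternatives were chosen before the data were examined. Alternatives were RLE factors, a DESeq2 Wald test, limma on the median over barcodes, DNA minimums of 40 and 400, no filter, 3 or 8 barcodes per allele, pseudocounts of 0.1 and 10, summed barcode ratios, leaving out the barcode with the highest ratio, the first run alone, leaving out the 3 MAX libraries, each library in turn, and the replicate number as a block. The block fits held only libraries whose number occurs in both groups compared. For sex, they matched females with males of the same number within a fraction, without the libraries of the other fraction. Block fits of allele interactions used limma. Alternatives added later are named in the closing section.

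Totals in mega-counts (M) were 27.4 to 40.4 M per DNA library and 39.4 to 85.7 M per RNA column. A count of 0 allows a share of up to 1.09e-05% in the DNA library with the fewest counts (3 counts of the total). Such limits cover counting error only, since reads carry no molecular identifiers. The comparisons were tested on simulated data with the same design, in which 67, 67 and 66 alleles or variants were changed by the sizes below at once. The Benjamini-Hochberg adjustment is less strict where many change, so a lone difference would be recovered less often than the shares given here. Of sex differences of 0.1, 0.2 and 0.4 log2 in total hippocampus, 53.7%, 79.1% and 97.0% were recovered, and of sex by allele differences of the same sizes 31.3%, 74.6% and 95.5%. With simulated barcode effects and no allele difference, 762 of 1086 variants (70.2%) passed across animals and 2 of 1086 across barcodes. The test across barcodes recovered 20.9%, 94.0% and 98.5% of allele effects of 0.3, 0.6 and 0.9 log2.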

Results

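The data hold the RNA level of 2724 reporter sequences in the hippocampus of female and male mice, each divided by the level of the same sequence in the injected virus. Most sequences are human DNA around a variant, cloned once with each allele, and per the series title the variants are linked to depression. The 20 RNA libraries fall in 4 groups of 5: female total hippocampus, male total hippocampus, female Vglut1 and male Vglut1, where Vglut1 means RNA on ribosomes of excitatory neurons. Female total libraries held 42.8 to 57.1 M counts, female Vglut1 libraries 47.5 to 78.9 M and male Vglut1 libraries 44.7 to 57.2 M. Male total columns held 39.4 to 85.7 M, and replicate 3 summed to 160.4 M over its 2 runs. The 4 DNA libraries held 27.4 to 40.4 M. Between RNA libraries, log2 RNA/DNA correlated across alleles at r = 0.753 to 0.930, and log2 CPM of the DNA libraries correlated across barcodes at r = 0.997 to 0.998. Within a group, the median SD of an allele between animals was 0.05 in female total, 0.04 in male total, 0.04 in female Vglut1 and 0.06 in male Vglut1 on the log2 scale.

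The first comparison asks which sequences drive more or less reporter RNA than the minimal promoter alone. Nearly all lay under Basal, read here as the promoter with no insert: 2718 of 2723 alleles and controls were lower and 4 higher. The median was -0.98 log2, with a range from -1.92 to 0.37. This does not show that inserts lower transcription, since what Basal holds is inferred, and the 9 other controls also lay under it. Both alleles of 2 variants were higher than Basal. At the PMFBP1 locus, named for a protein of the sperm neck, rs4788563 with A stood 0.37 above Basal (SE 0.0079) and with C 0.36 (SE 0.0087). At TMEM161B-MEF2C-Blk1, near the gene of the neuronal transcription factor MEF2C, rs142841971 with the deletion allele stood 0.30 above Basal (SE 0.0093) and with TG 0.29 (SE 0.0093). All 4 were above Basal in 20 of 20 libraries.

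Among alleles past the threshold, the next lay just under Basal. At the ZNF445 locus, named for a zinc finger protein, rs6771160 with G was at -0.03 (SE 0.0101), and rs11130025 was at -0.06 with C and at -0.09 with A. At DUSP6, the gene of a phosphatase of ERK kinases, rs12300350 was at -0.05 with A and at -0.07 with T. At SIRT1, the gene of an NAD-dependent deacetylase, rs7096745 with A was at -0.14. The lowest alleles were BRAF-Blk1 rs11763409 with C at -1.92 (SE 0.06, 5 barcodes), TMEM161B-MEF2C-Blk2 rs2304608 with A at -1.73 (SE 0.03), LIN28B rs1475120 with A at -1.68 (SE 0.04), MDDLateMale rs4753141 with A at -1.66 (SE 0.03) and ZNF445 rs200759800 with the deletion allele at -1.62 (SE 0.03). Of the controls, NRSE, a binding site of the neuronal repressor REST, was at -0.39, the Flt1 fragment at -0.46 and the proximal promoter of the neuronal gene SYN1 at -0.57. The Hb9 enhancer was at -1.02, and 5 elements named as top CREs lay between -1.17 and -0.77.

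In edgeR 2722 of 2723 passed, and the exception was RERE rs301807 with G, at -0.0071 (adjusted p = 0.345), named after its values were seen. With barcodes as replicates, a test added after the data were seen, 2707 alleles were lower and 4 higher than the 110 Basal barcodes (SD 0.376 between Basal barcodes). The 4 were the same PMFBP1 and TMEM161B-MEF2C-Blk1 alleles, at 0.28 (SE 0.0914), 0.34 (SE 0.0691), 0.29 (SE 0.110) and 0.30 (SE 0.0955), with adjusted p of 0.00695, 0.000154, 0.0182 and 0.00664. The 5 lowest alleles passed too, but with wider SEs and in another order. They were at -1.57 for rs11763409 (SE 0.265, 5 barcodes), -1.71 for rs2304608 (SE 0.144) and -1.55 for rs1475120 (SE 0.254, 8 barcodes). The others were at -1.32 for rs4753141 (SE 0.149, 8 barcodes) and -1.49 for rs200759800 (SE 0.103, 7 barcodes). The 6 named alleles just under Basal did not pass across barcodes, with adjusted p from 0.0566 to 0.572. Of these, rs11130025 with A was at -0.66 across barcodes (SE 0.347), far lower than on the summed counts, and the other 5 lay between -0.14 and -0.05. Relative to the median allele, which was also added later, these 6 were higher, rs6771160 with G by 0.94 for example, and 1189 alleles were higher and 1159 lower in all.

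**Figure D1:**
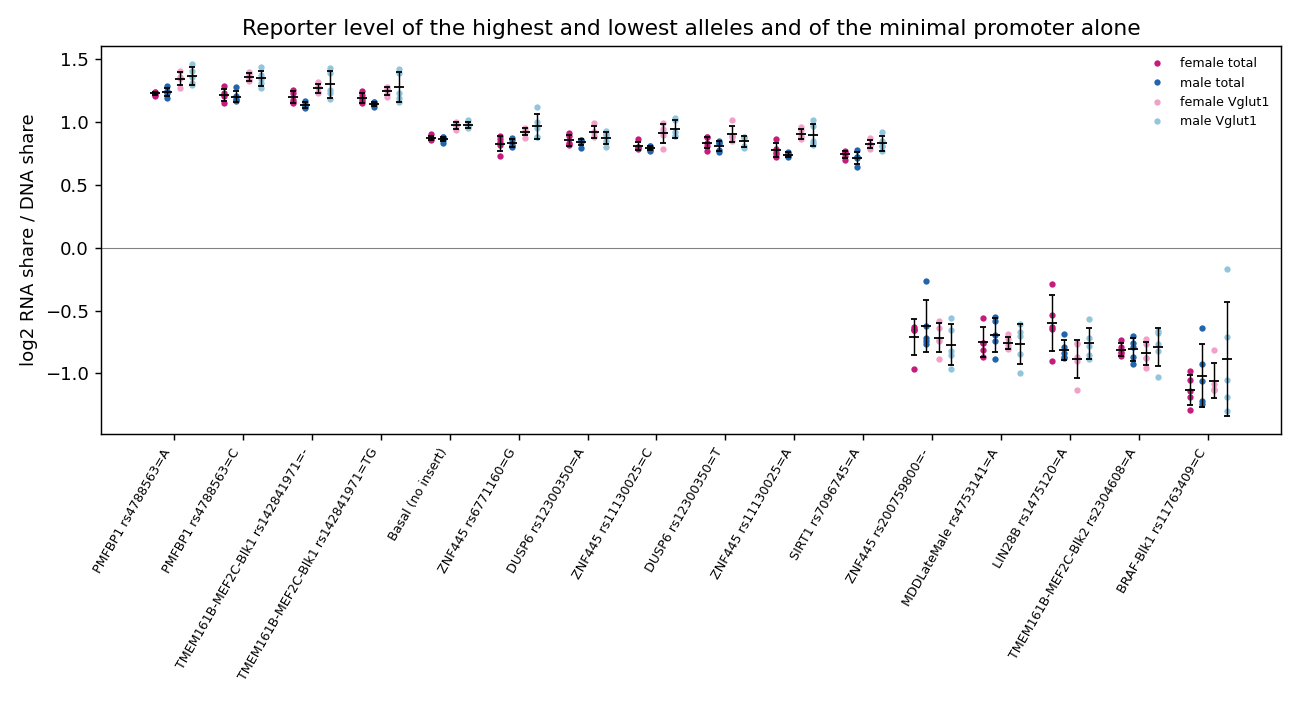
log2 of RNA share over DNA share (y axis) for the 10 highest and 5 lowest alleles among those past the threshold against Basal, and for Basal. Each library is 1 point, coloured by group, with black marks for the mean and SD of each group (n = 5). The 4 alleles on the left lie above Basal in all 20 libraries.

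Sequence composition went with activity. Across variants, GC content correlated with activity at r = 0.326 (Spearman's rho 0.266), over variants that are not independent replicates. The 335 variants with a GC content of at least 52.0% were higher than the others, with a median of 0.13 against -0.04 relative to the median variant (camera, adjusted p = 2.19e-09). The 289 variants with at least 4 CpG had a median of 0.11 against -0.02 (adjusted p = 3.82e-05), and the 67 with an SP1/KLF site, a GC box of many promoters, a median of 0.08 against -0.0049 (adjusted p = 0.0396). With an estimated correlation the GC and CpG lists passed (adjusted p = 8.98e-06 and 0.000153) and the SP1/KLF list did not (adjusted p = 0.0764). An SP1/KLF site is itself made of G and C and holds a CpG, and no list was adjusted for GC content. These lists are therefore not separate lines of support. The other 18 of the 21 lists tested did not pass. They were AP-1, NeuroD/E-box, E-box, SOX, FOX, POU, homeobox, TATA box, CCAAT box, nuclear receptor half-site, androgen or glucocorticoid half-site, STAT, NF-kB, TCF/LEF, HSF, GATA, NFAT and low GC content. The 15 lists with under 10 variants, among them CRE, MEF2, REST core, CTCF and the full oestrogen response element, were not tested. For sex in total, sex in Vglut1 and fraction, 0 of 21 lists passed in camera with either correlation, with lowest adjusted p of 0.842, 0.854 and 0.755 with the preset and 0.705, 0.658 and 0.394 with the estimated correlation.

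The next comparison asks which variants change activity. The largest supported effects were at RERE, the gene of a transcriptional corepressor, and at ZNF445. At RERE rs301807, reporters with G were higher than with A by 0.61 log2 in Vglut1 (SE 0.110 across 10 barcodes per allele, adjusted p = 0.0124). Mean log2 RNA/DNA per barcode was 0.95 ± 0.26 (SD) with G and 0.34 ± 0.22 with A. At ZNF445 rs7653558, reporters with T were lower than with C by 0.55 (SE 0.109, adjusted p = 0.0251), at -0.18 ± 0.31 and 0.37 ± 0.13. Across animals, both effects had the same sign in 5 of 5 libraries of each of the 4 groups. Every library reads the same barcodes, so this agreement adds no support for an allele effect over a barcode effect. In total hippocampus the differences across barcodes were 0.55 (SE 0.112, adjusted p = 0.0596) and -0.51 (SE 0.110, adjusted p = 0.0652). The third smallest p there was that of RERE rs10779702, with G at -0.47 against A (SE 0.118, adjusted p = 0.220).

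Across barcodes, limma's moderated test passed these 2 variants of 1286 in Vglut1 (74 at an unadjusted p under 0.05) and 0 in total hippocampus (81 at an unadjusted p under 0.05). An exact rank-sum test across barcodes, added later, passed 0 in both. In Vglut1 its adjusted p was 0.0974 for RERE rs301807 and 0.139 for ZNF445 rs7653558. With 10 barcodes per allele and 1286 variants, it lets a lone variant pass only where the barcodes of both alleles hardly overlap. Its 0 therefore says little against these effects. In total hippocampus, both variants passed without female total replicate 1 (adjusted p = 0.0379) and without female total replicate 2 (0.0401), and RERE rs301807 alone without male total replicate 4 (0.0371). With summed RNA against summed DNA per barcode both passed there as well (adjusted p = 0.0443). With a pseudocount of 10, both (adjusted p = 0.00305 and 0.0366) and RERE rs10779702 (0.0425) passed. Across animals, edgeR passed 886 variants in total hippocampus (432 with allele 2 higher, 454 lower) and 888 in Vglut1 (434 higher, 454 lower), with a median size of 0.13 and 0.14 among those that passed. These counts do not separate an allele effect from a barcode effect shared by all animals. Over 1286 variants, the activities of both alleles correlated across variants, which are not independent replicates, at r = 0.747 (Spearman's rho 0.698).

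**Figure D2:**
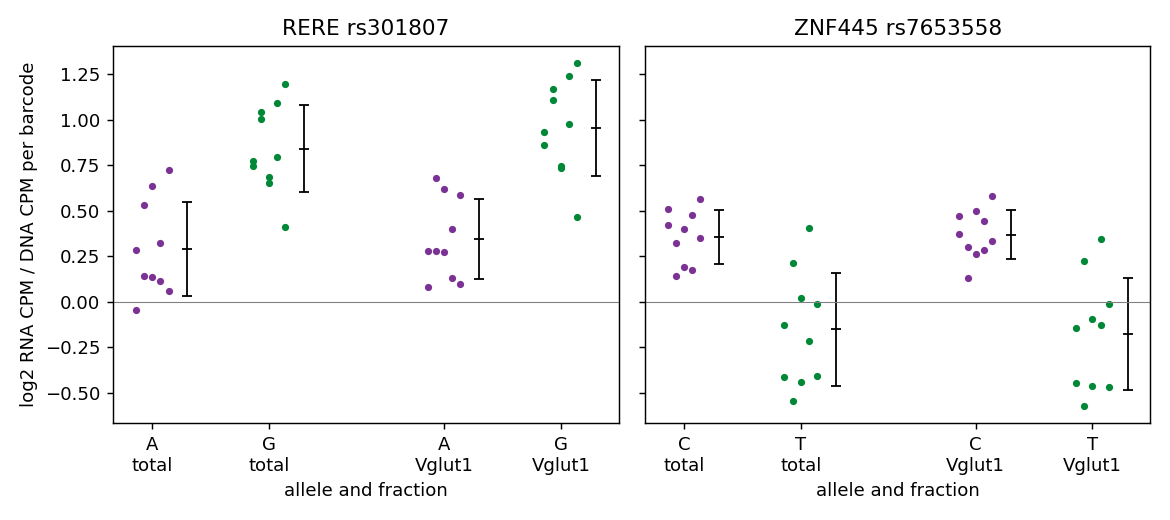
Mean log2 RNA CPM over DNA CPM of each barcode (y axis) for both alleles of RERE rs301807 and ZNF445 rs7653558 in total hippocampus and in Vglut1 (x axis), with 1 point per barcode and black marks for the mean and SD over 10 barcodes. The G barcodes of rs301807 average 0.84 in total and 0.95 in Vglut1, against 0.29 and 0.34 for A.

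Motif-bearing alleles were compared with the other allele of the same variant to ask whether gaining a site moves activity 1 way. With a CCAAT box, the site of the promoter factor NF-Y, the mean of 32 variants was -0.06 in total hippocampus (SE 0.0238, 10 higher and 22 lower, permutation adjusted p = 0.112) and -0.06 in Vglut1 (SE 0.0228, 9 higher and 23 lower, permutation adjusted p = 0.0674). In total and Vglut1, the means were 0.03 and 0.05 for SP1/KLF, -0.04 and -0.06 for SOX, -0.15 and -0.09 for homeobox, and 0.04 and 0.07 for the nuclear receptor half-site. For the androgen or glucocorticoid half-site they were -0.01 and 0.0034, for GATA 0.06 and 0.04, and for NFAT -0.01 and -0.0075. After adjustment over the 8 lists, 0 passed the permutation test in either fraction, and the CCAAT box alone had an unadjusted permutation p under 0.05 (0.0140 in total and 0.00843 in Vglut1). Without male Vglut1 replicate 1 it passed in Vglut1, at -0.07 (permutation adjusted p = 0.0497).

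The fraction comparison asks which reporters differ between the pull-down, aimed at ribosome-bound RNA of excitatory neurons, and total RNA. The counts hold only reporter barcodes, so how far the pull-down enriched RNA of these cells was not checked. In Vglut1, 124 alleles and controls were higher and 65 lower, by at most 0.15 and -0.11 log2. The promoter alone was higher by 0.10 (SE 0.0071, 10 libraries per fraction). The largest rises were at ZNF445 rs6770567 with G (0.15, SE 0.0138), TCF4-Superblock-Blk2 rs9807185 with T (0.15, SE 0.0160), ZNF445 rs6771160 with C (0.15, SE 0.0234), ZNF445 rs11130025 with A (0.14, SE 0.0205) and PMFBP1 rs4788563 with C (0.14, SE 0.0181). TCF4 encodes a helix-loop-helix transcription factor of neurons. The largest falls were at ZNF445 rs1868603 with C (-0.11, SE 0.0327), MAT2B-TNM2 rs1368418 with T (-0.10, SE 0.0277), PMFBP1 rs11075908 with C (-0.09, SE 0.0220), ESR2 rs1256113 with C (-0.09, SE 0.0204) and PTGER3-Blk2 rs11434745 with the deletion allele (-0.08, SE 0.0207). Each of the 5 rises held in 10 of 10 Vglut1 libraries against the mean of total. Of the 5 falls, 3 held in all 10, rs1368418 was above that mean in 1 library and rs1868603 in 2.

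The differences grew with activity. Of the 124 higher alleles, 112 were above the median allele in activity, against 20 of the 65 lower ones, and the slope of the fraction difference on activity was 0.0624 over all alleles. A library's slope on the mean of the others was 1.03 ± 0.032 (SD, n = 10) in Vglut1 and 0.963 ± 0.011 in total. The 3 highest were those of the MAX libraries, male Vglut1 4 (1.09), male Vglut1 6 (1.06) and female Vglut1 4 (1.06), and the next was 1.04. In edgeR, 189 of 2724 passed (505 at an unadjusted p under 0.05), with adjusted p between 2.60e-12 and 0.0316 for the named alleles. Limma on the median over barcodes passed 35. With each library's linear scaling in the offset, added later, 133 passed (72 higher, 61 lower), 78 of them among the 189. The 5 named rises passed with it but shrank, to 0.10 for rs6770567, 0.12 for rs9807185, 0.09 for rs6771160, 0.08 for rs11130025 and 0.07 for rs4788563, and Basal shrank to 0.04. They passed in 33 of 33 alternatives, while each of the 5 falls was lost in at least 1. With scaling, the falls at ZNF445 rs1868603 (-0.12, adjusted p = 0.0120), PMFBP1 rs11075908 (-0.10, 0.00327) and PTGER3-Blk2 rs11434745 (-0.08, 0.00850) passed, and MAT2B-TNM2 rs1368418 (-0.08, 0.0990) and ESR2 rs1256113 (-0.06, 0.0697) did not. With limma, rs1368418 (0.120), rs1256113 (0.452), PMFBP1 rs11075908 (0.0746) and PTGER3-Blk2 rs11434745 (0.361) did not. Without the barcode with the highest ratio, rs1368418 (0.1005) and rs1868603 (0.0934) did not. Over all alternatives the adjusted p of the falls ran from 0.000136 to 0.452. The rs1868603 call passed in 24 of 33 alternatives, and among left-out libraries it was lost without female total replicate 5 (adjusted p = 0.0669), male total 3 (0.0593), 4 (0.0644) or 5 (0.0689), female Vglut1 3 (0.0885) or 4 (0.0545) or male Vglut1 2 (0.0512).

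**Figure D3:**
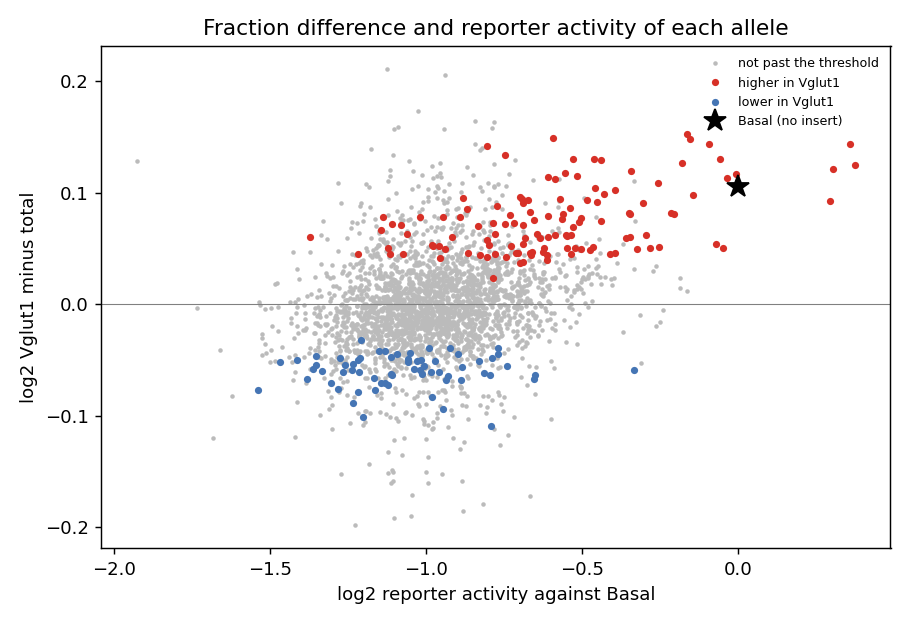
Vglut1 minus total in log2 (y axis) against activity relative to Basal in log2 (x axis), with 1 point per allele or control. Red points are the 124 higher and blue points the 65 lower in Vglut1, and the star is Basal at 0.10.

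The series asks whether the sexes differ, first in the level of each reporter. In the Vglut1 fraction, 1 allele differed: ESR2 rs34781508 with the deletion allele was lower in females by 0.11 log2 (adjusted p = 0.0139). ESR2 encodes oestrogen receptor beta. Mean log2 RNA/DNA was 0.11 ± 0.03 (SD, n = 5) in females and 0.22 ± 0.05 (n = 5) in males, with 5 of 5 females below the male mean. In total hippocampus its means were 0.13 ± 0.03 and 0.13 ± 0.04. The G allele of the same variant was at 0.51 ± 0.06 in female and 0.56 ± 0.06 in male Vglut1 (adjusted p = 0.773). In total hippocampus the smallest p belonged to ESR2 rs28666045 with C (-0.06, SE 0.0173), ZNF445 rs6769609 with C (0.06, SE 0.0195) and BRAF-Blk1 rs28498721 with C (-0.07, SE 0.0225), female minus male, which did not pass (adjusted p = 0.992).

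In total hippocampus, edgeR, DESeq2 and limma each passed 0 of 2724, with 126 at an unadjusted p under 0.05 in edgeR. In Vglut1 edgeR and DESeq2 passed 1 and limma 0, with 171 at an unadjusted p under 0.05 in edgeR. The ESR2 call was lost without female Vglut1 replicate 1 (-0.11, adjusted p = 0.101), 4 (-0.11, 0.116) or 6 (-0.11, 0.107), without male Vglut1 replicate 2 (-0.11, 0.0519) or 6 (-0.10, 0.0963), and without the 3 MAX libraries (-0.09, adjusted p = 0.423). The call was also lost with the replicate block (-0.11, edgeR adjusted p = 0.918) and in the same samples without the block (-0.11, 0.970). Both fits held only Vglut1 libraries whose number occurs in both sexes, and the block matched females with males. As the call was lost without the block too, its loss does not need that matching. The sex difference differed between fractions for no reporter past the threshold: edgeR, DESeq2 and limma each passed 0 of 2724, with 115 at an unadjusted p under 0.05 in edgeR. The smallest p there belonged to LIN28B rs4946652 with T (0.12, SE 0.0316), ESR2 rs34781508 with the deletion allele (-0.11, SE 0.0316) and SLC6A15 rs2446665 with T (0.10, SE 0.0287), each with an adjusted p of 0.885.

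The question of whether an allele effect differs between the sexes gave 1 variant in Vglut1. At TMEM161B-MEF2C-Blk2 rs26582, G minus A was -0.07 ± 0.05 (SD, n = 5) in females and 0.15 ± 0.11 (n = 5) in males. All 5 female Vglut1 libraries lay below 0 and all 5 male ones above. The difference was -0.22 (SE 0.0483, edgeR adjusted p = 0.0438). In total hippocampus the same effects were -0.01 ± 0.07 and 0.03 ± 0.09. The smallest p in total hippocampus belonged to RSRC1 rs3836407 (-0.11, SE 0.0307, adjusted p = 0.653), LIN28B rs4504502 (0.09, SE 0.0302) and TMEM161B-MEF2C-Blk1 rs5869417 (-0.13, SE 0.0414), the latter pair with an adjusted p of 0.991.

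In Vglut1, edgeR passed 1 of 1286 (100 at an unadjusted p under 0.05) and DESeq2 2, the second being BRAF-Blk1 rs62485368 (-0.21, adjusted p = 0.00409), named after its values were seen. Limma passed 4, also named after their values were seen: RSRC1 rs9847460 (-0.34), rs62485368 (-0.27), BRAF-Blk1 rs6662 (-0.20) and MAD1L1 rs12534131 (-0.19). In total hippocampus, edgeR, DESeq2 and limma each passed 0, with 50 at an unadjusted p under 0.05 in edgeR. The rs26582 call was lost without female total replicate 1 (adjusted p = 0.0560) or 3 (0.0547) or male total 3 (0.0566), 5 (0.0581) or 6 (0.0520), where the difference stayed at -0.22, since total libraries are not in the contrast itself but share its estimate of spread. It was also lost without female Vglut1 1 (-0.20, 0.172), 4 (-0.21, 0.215), 5 (-0.22, 0.0742) or 6 (-0.22, 0.0570), or male Vglut1 1 (-0.21, 0.123), 4 (-0.18, 0.225) or 6 (-0.20, 0.0733). Without female total 2, rs62485368 passed as well (-0.21, adjusted p = 0.0475). Without the 3 MAX libraries the rs26582 difference was -0.14 (SE 0.0514, adjusted p = 0.868).

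**Figure D4:**
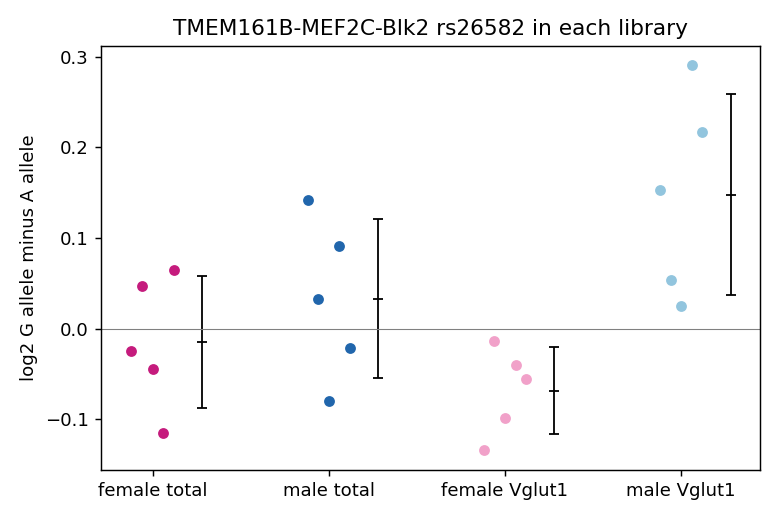
G minus A in log2 (y axis) at TMEM161B-MEF2C-Blk2 rs26582 in each library of the 4 groups (x axis), with black marks for the mean and SD (n = 5). Female Vglut1 libraries average -0.07 and male ones 0.15.

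Allele effects were last compared between fractions. The smallest p belonged to PMFBP1 rs12149325 with G minus C (-0.07, SE 0.0193), TCF4-Superblock-Blk2 rs8097335 with T minus C (0.03, SE 0.00998) and BRAF-Blk1 rs73165483 with T minus G (-0.05, SE 0.0154), Vglut1 minus total. At rs73165483, T minus G was 0.17 in total (SE 0.0109) and 0.12 in Vglut1 (SE 0.0109). In edgeR 0 of 1286 passed, and in limma 0 (edgeR lowest adjusted p = 0.304, 113 at an unadjusted p under 0.05). DESeq2 passed 5: rs73165483 (adjusted p = 0.0422) and, named after their values were seen, PCDHAs rs72798896, RSRC1 rs73172122, ZNF445 rs13100967 and ESR2 rs10145001, at 0.06, -0.07, 0.05 and 0.07.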

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

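No test in this part was chosen only after its result was seen, but the bound for leaving out the 3 MAX libraries and for leaving out 1 barcode, that the share kept exceed 50% by more than its spread, was added after a first run. In the groups of 5 libraries, 17 of 168 had a library far from the other 4 (10.1%, where chance gives about 5%). At DUSP6 rs12300350, A was at 0.79 log2 RNA/DNA in male total 6 (others 0.84 to 0.86) and T at 1.02 in female Vglut1 4 (others 0.85 to 0.89). ZNF445 rs11130025 with C was at 0.86 in female total 3 (others 0.79 to 0.80), and rs6769609 with C at 0.27 in male Vglut1 6 (others 0.19 to 0.21). ZNF445 rs200759800 with the deletion allele was at -0.97 in female total 1 (others -0.66 to -0.63) and at -0.26 in male total 6 (others -0.76 to -0.62). BRAF-Blk1 rs11763409 with C was at -0.81 in female Vglut1 5 (others -1.13 to -1.08), and TCF4-Superblock-Blk2 rs9807185 with T at 0.52 in male Vglut1 6 (others 0.36 to 0.40). MAT2B-TNM2 rs1368418 with T was at -0.28 in male total 4 (others -0.20 to -0.18), PTGER3-Blk2 rs11434745 with the deletion allele at -0.28 in male Vglut1 6 (others -0.08 to -0.02), and LIN28B rs4946652 with T at -0.24 in male total 6 (others -0.19 to -0.17). The allele difference was -0.14 at TMEM161B-MEF2C-Blk1 rs5869417 in male total 2 (others -0.21 to -0.20), -0.14 at PMFBP1 rs12149325 in male total 6 (others -0.08 to -0.07) and 0.57 at RERE rs301807 in male total 4 (others 0.60 to 0.61). Basal was at 0.90 in female total 2 (others 0.86 to 0.87). Depth was 160.4 M in male total 3, which sums 2 runs (others 39.4 to 70.9), and 78.9 M in female Vglut1 4 (others 47.5 to 53.9).

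RNA counts also appeared for barcodes with no DNA count, which no comparison uses. Of 1685 such barcodes, 51 had over 3 counts in some RNA column, and the highest sum over the 21 RNA columns was 55.

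In Vglut1, the G minus A effect of TMEM161B-MEF2C-Blk2 rs26582 differed between the sexes by -0.22, and ESR2 rs34781508 with the deletion allele differed in level. A single barcode was argued against as the source of most of the difference at rs26582: without the barcode that adds most, 82.8% was left. The call itself is less firm. Without the barcode with the highest ratio of each allele, the difference was -0.18 (SE 0.0527) and no longer passed (edgeR adjusted p = 0.474). The 3 MAX libraries remain a possible explanation, since without them 63.8% of the difference was left (-0.14, SE 0.0514), which exceeds 50% by less than its spread. Chance was not excluded either. Of 100 regroupings of the sex labels, 8 gave at least the 1 call at the sex by allele test (highest other 2) and 13 at least the 1 call at the sex test (highest other 11). A biological difference between the sexes stays open.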

How the results depend on the processing

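The alternatives centred on the median allele, barcodes as replicates for activity, the linear scaling, the exact rank-sum test, the samples of the replicate block fitted without it, and leaving out libraries for the sequence and motif lists were chosen after seeing the data. Of 1543 recomputed values for 49 named results, 1474 kept direction and side of the threshold, 52 no longer passed, 11 newly passed and 6 reversed. Those 6 reversed when centred on the median allele instead of Basal, which moves the zero point: ZNF445 rs6771160 with G 0.94, rs11130025 with C 0.92 and A 0.89, DUSP6 rs12300350 with A 0.93 and T 0.91, and SIRT1 rs7096745 with A 0.83. For the changed counts below the cause was not tested. Sex in Vglut1 gave 0 with limma, without the 3 MAX libraries, with the replicate block (ESR2 rs34781508 -0.11, adjusted p = 0.918, range 0.000745 to 0.970 over its alternatives) and with the same samples without the block. Those samples are only the Vglut1 libraries whose number occurs in both sexes. Sex by allele in Vglut1 gave 2 with DESeq2, 4 with limma, and 0 with no filter, with at least 8 barcodes, without the barcode with the highest ratio, without the MAX libraries and with the block, fitted in limma. Fraction gave 35 with limma. Fraction by allele gave 5 with DESeq2. The motif-bearing test gave 1 with a minimum of 400 DNA counts (the CCAAT box in total, -0.07, permutation adjusted p = 0.0380). Across barcodes, total gave 3 with a pseudocount of 10 (RERE rs301807, ZNF445 rs7653558 and RERE rs10779702, the last named after its values were seen) and 2 with summed RNA (the first pair), and Vglut1 gave 0 with the exact rank-sum test. Leaving out each library in turn gave 2722 to 2722 for activity, 0 to 1 for sex in Vglut1, 135 to 211 for fraction, 850 to 909 and 857 to 896 for allele effects in total and Vglut1, 0 to 2 for sex by allele in Vglut1, 0 to 2 and 2 to 2 across barcodes in total and Vglut1, 3 to 3 for sequence lists and 0 to 1 for motif-bearing alleles. It gave 0 to 0 in edgeR for sex in total, sex by fraction, sex by allele in total and fraction by allele, with the unadjusted counts given in the report. Per the labels the supernatant was split between the fractions, so that both can come from the same animals, but they do not say which libraries share an animal. Replicate numbers were therefore not read as pairs in the main fits, though the values go with pairing. The 8 pairs of the same number and sex across fractions correlated at 0.0226 to 0.0714 (median 0.0299), and 0 exceeded 0.1. The 42 pairs of different number ran from -0.0752 to 0.0710 (median -0.0084). Of 16 libraries with a partner of the same number, 14 correlated best with it, so that a number may mark an animal. These 16 are the members of the same 8 pairs, so their matches are not independent. The tests of fraction, sex by fraction and fraction by allele and their regroupings treat all libraries as independent, which is a limit. With the replicate block, fraction gave 182, against 152 in the same samples without it, where ZNF445 rs1868603 did not pass (its adjusted p ran from 0.0113 to 0.0934 over all alternatives). Depth limits the barcodes with few DNA counts.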

Other observations

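The locus tests, the overlap of sequences, the total count of calls after linear scaling, the regroupings of that fit and the test near the median activity were chosen only after the results were seen, as was counting earlier calls in the scaling test. Of 25 loci tested with camera for activity, 2 passed: LHPP, named for a phosphatase (24 variants, median 0.10 against -0.0030, adjusted p = 0.0328, 0.0824 with an estimated correlation), and MAD1L1, named for a spindle checkpoint protein (88 variants, 0.10 against -0.0051, adjusted p = 0.0376, 0.0258 with an estimated correlation). For fraction, camera passed 0 of the 25 loci with either correlation (lowest adjusted p 0.509 with the preset, with 0 at an unadjusted p under 0.05, and 0.418 with the estimated correlation). By count, ZNF445 had 20 of 225 alleles higher in Vglut1 and 6 lower, MAD1L1 13 of 176 and 5 lower, and PCDHAs 11 of 130 and 2 lower, against 124 of 2724 higher and 65 lower in all. Other loci of similar or larger size had fewer higher, with 8 of 265 at LIN28B (8 lower), 9 of 221 at RSRC1 (8 lower) and 2 of 205 at SLC6A15 (3 lower). The smaller NEGR1 locus, named for a neuronal adhesion molecule, had 6 of 35 (1 lower). At ZNF445 the median fraction difference was -0.0087 against -0.0061 elsewhere (adjusted p = 0.994). Among 243 pairs of variants that share a run of 30 bases, activity correlated at r = 0.243 across pairs, which are not independent replicates.

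Many variants passed the allele test across animals, 886 in total hippocampus, and 0 across barcodes there (limma, 81 at an unadjusted p under 0.05). The exact rank-sum test, which a lone variant can hardly pass, also gave 0. A candidate explanation is a barcode effect shared by all animals. The barcodes of 1 allele, split at random into 2 sets and tested like alleles, passed in 74.6% of 1865 alleles, against 76.0% of 889 variants, a ratio of 98.1%. Flipping allele labels in random libraries gave at most 664 variants in total and 665 in Vglut1 (886 and 888 real, 1 of 100 in each). Every library reads the same barcodes, so a barcode effect alone also gives most calls with the real labels. The flips therefore cannot tell an allele effect from a structure that follows the sequences, and no conclusion is drawn from them. With simulated barcode effects and no allele difference, 70.2% of 1086 variants passed across animals, against 68.9% of 1286 in total hippocampus in the data. Barcode effects alone can thus give a count of this size, and how many variants hold an allele effect stays open.

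The differences between fractions grew with activity, and a linear scaling of each library was weighed as the source. With it in the offset, 78 of the 189 earlier calls were still made and the slope on activity went from 0.0624 to -0.0245. Basal went from 0.10 (SE 0.0071) to 0.04 (SE 0.0058). The prediction, written before, spoke of calls that remain, and the total of 133 calls (72 higher, 61 lower) would have met its bound against scaling. Reading it as earlier calls still made was chosen after that total was seen, because new calls are not calls that remain, so scaling may account for part of the pattern and the reading is a limit. As the whole source of the fraction calls, linear scaling is argued against by the 1014 alleles within 0.1 of the median activity, where it moved no allele by more than 0.011 log2. With it, 28 of these passed (12 higher, 16 lower, median size 0.06), 24 of them among the earlier calls, and regroupings of the same fit gave at most 6. Over all alleles, regroupings of that fit gave at most 32 against the 133. The 3 MAX libraries had the 3 highest library slopes (1.09, 1.06 and 1.06, next 1.04), and without them the slope on activity kept 75.5% of its size (jackknife SE 5.51), so they are argued against as the whole source and may add to it. RNA class and cell type differ together between the fractions and stay open.

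Regroupings of the labels, 100 for each test with the real one included, gave the following. For fraction, 1 gave as many calls as the 189, and the highest other was 4. Across barcodes in Vglut1, 1 gave as many as the 2, and the highest other was 0. Chance is argued against for these only at 1 in 100, the smallest share that 100 regroupings can give. For fraction, libraries that may share an animal were regrouped as independent. Across barcodes in Vglut1, the exact rank-sum test passed 0, but a lone variant can hardly pass it. Where 0 passed, all 100 gave as many, with a highest other of 1 for sex in total, 9 for sex by fraction, 1 for sex by allele in total, 0 for fraction by allele and 0 across barcodes in total (unadjusted counts and the other tools are in the report).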
